A study of Mus musculus with 6 samples.

How the data were processed

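RNA sequencing was done on pools of 4T1 cells, a mouse mammary tumour cell line, that were wild type (WT) or knockout (KO) for Myo1e, the gene of the class I myosin motor protein myosin 1e. Each genotype had 3 libraries. Per the labels' protocols, total RNA came from a column kit and libraries from a stranded mRNA preparation, and the series' design text calls the samples biological replicates. How the knockout was made and how the pools were derived is not given in the sources used here.

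The deposited table holds log2 CPM values, the log2 of reads scaled to an effective library size (CPM) with a prior added, for 11452 gene symbols in 6 columns. Per the submitters' processing notes, the authors used Trimmomatic 0.39, STAR 2.7.3a, featureCounts of Subread 1.6.4 and edgeR, with genome build GRCm38. The strand setting of the counting, the annotation release and the normalization are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies, such as the classical MHC class I genes, can therefore be misassigned in these values. Every gene in the table has a log2 CPM of at least 0 in at least 2 libraries, so genes below that level were not measured here.

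The columns are numbered 1, 2 and 4 in each genotype, whereas the sample titles count pools 1 to 3. Columns 1 and 2 were matched to pools of the same number, and the columns numbered 4 were matched to their genotype only. Libraries are named here by genotype and column number, as KO 4 or WT 4.

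The deposited log2 values turned out to hold whole reads. After the lowest linear value was subtracted, all linear values of a library were multiples of a single step within a tolerance of 0.01, with a prior count of 1 and a log2 value of -4.25 for 0 reads. The reads recovered this way numbered 17772003 to 19988206 per library. A count of 0 reads allows a level of up to 0.144 to 0.173 CPM, taking 3 reads as the limit. This limit covers counting error only.

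The comparison was KO against WT, fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 CPM, with a moderated variance that follows the mean and no further covariate. Genes needed a log2 CPM of at least 0 in at least 3 of the 6 libraries, which left 11269 genes and dropped 183. Tests were two-sided, and a Benjamini-Hochberg adjusted p of 0.05 was the threshold. Fold changes are on the log2 scale with the authors' prior, which understates changes of weakly expressed genes. Levels are given as mean ± SD over the 3 libraries of a genotype. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so the model across genes was used.

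Before the data were examined, 37 gene lists were fixed: myosins and actin regulators, adhesion, cell identity, cell cycle, interferon and antigen presentation, signalling targets, metabolism, stress responses, and markers of other cell types and of RNA quality. Lists were tested with limma's camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation and limma's fry were the alternatives. The rule for named genes, fixed at the same time, took Myo1e, the 12 genes with the largest and the 12 with the smallest log2 change past the threshold, and up to 4 members of each list with the smallest p. No gene met the rule on size. Some genes that met the other parts of the rule are not reported here. Any other gene was chosen after its values were seen, as stated where it appears.

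Whether the column numbers pair the libraries was checked from the deviations of each library from its genotype mean. The correlations of same-numbered KO and WT deviations across genes were 0.744, 0.784 and 0.921 for the numbers 1, 2 and 4, and each KO library correlated best with the WT library of its own number. Much of this comes from the libraries numbered 4, since KO 1 with WT 2 and KO 2 with WT 1 also correlated, at 0.687 and 0.617. Without the libraries numbered 4, the difference between libraries 1 and 2 in KO correlated with that in WT at r = 0.256 across 11269 genes, which are not independent replicates. The numbers were taken to pair the samples on these values and not from a label, with less support for 1 and 2 than for 4. A fit with the number as a replicate block was computed for every result. It is given beside a result where it changes a call or a count.

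The other alternatives fixed in advance were no filter, a minimum of log2 CPM 1, pseudocounts of 1 and 0.25, median centring, quantile normalization, an untrended or robust variance, and leaving out each library in turn. A further one tested the lists without genes that another list holds. Leaving out 1 library leaves the numbers 1, 2 and 4 in unequal shares of the genotypes. Lists on which the libraries numbered 4 stand apart then move by construction. Alternatives chosen after seeing the data were limma voom on the recovered reads, a term for the libraries numbered 4, libraries 1 and 2 only, a correction for transcript length and GC content, and the replicate block joined to an estimated correlation or to fry in the list tests. Lengths and GC content came from GENCODE M21, in which 99.1% of symbols had a transcript length. For each library the trend on both, fitted by loess with a span of 0.5, was subtracted.

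The fits were tested on simulated data for KO against WT, with 5 simulations of 11269 genes and 200 changed genes in each. Without the block, 0.299% of genes changed by log2 0.5, 30.7% of 2-fold changes and 67.3% of 4-fold changes were recovered, with 0 false calls. With the replicate block the shares were 91.0%, 97.9% and 99.7%, with 48 false calls among 55225 unchanged genes. A list shifted by log2 -0.3 was called in 5 of 5 simulations by both fits, and 0 of 185 unshifted lists were called. Simulated genes varied independently, so these list results do not cover genes that vary together. All simulated genes also had the same dispersion, 0.00122, and the libraries numbered 1 and 2 had the same mean. The recovered shares therefore do not cover genes that vary more than this, and a low count of called genes does not exclude other changes.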

Results

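The transcriptomes of Myo1e knockout and wild-type 4T1 cell pools were compared, with 3 libraries per genotype. The recovered reads numbered 19988206 in KO 1, 17772003 in KO 2 and 19560010 in KO 4. They numbered 19697034 in WT 1, 19129743 in WT 2 and 17980487 in WT 4. Mitochondrially encoded genes held 0.493%, 0.416% and 0.343% of the reads in KO 1, KO 2 and KO 4, and 0.435%, 0.379% and 0.309% in WT 1, WT 2 and WT 4. The chi-square per degree of freedom between any 2 libraries was 5.06 or more, which is above sampling noise for every pair of libraries.

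The largest difference in the data was between library numbers and not between genotypes. The first principal component held 83.8% of the variance and placed KO 4 and WT 4 at 48.4 and 49.2, and the other 4 libraries between -27.7 and -20.4. Across genes, KO 4 and WT 4 correlated at r = 0.995, and each correlated at 0.951 or less with every library numbered 1 or 2. Both genotypes hold 1 such library, so the number and the genotype can be separated.

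**Figure D1:**
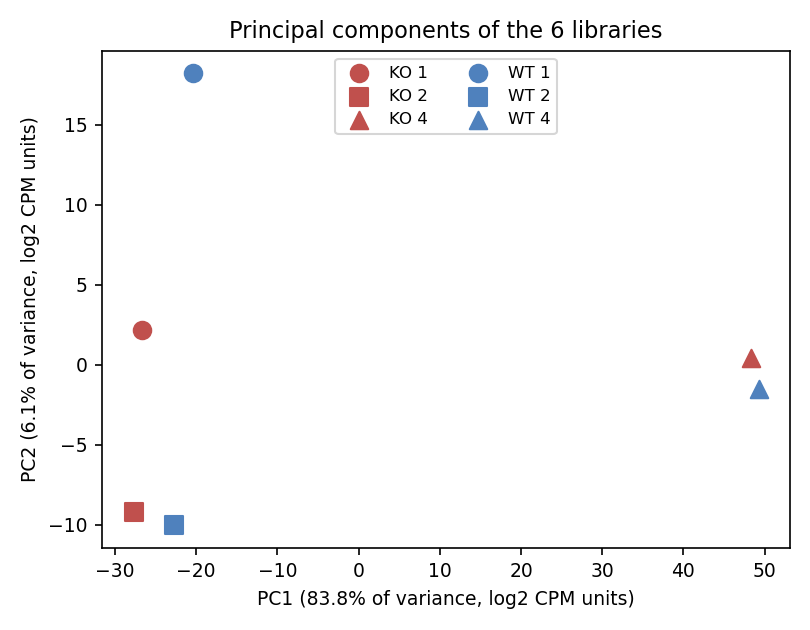
First and second principal components of log2 CPM in the 6 libraries, with KO in red, WT in blue and a symbol for each library number. The libraries numbered 4 lie at 48.4 and 49.2 on the first component, which holds 83.8% of the variance, and the other 4 lie at -20.4 or below.

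The targeted gene was examined first. Myo1e (GRCm38 chromosome 9, 70207350 to 70399766, plus strand) was expressed at 6.83 ± 0.03 log2 CPM in KO and 7.01 ± 0.09 in WT (SD, n = 3). Its level was 6.87, 6.81 and 6.81 in KO 1, KO 2 and KO 4, and 7.09, 7.02 and 6.91 in WT 1, WT 2 and WT 4. The difference was -0.18 (SE 0.09), lower in 3 of 3 pairs by -0.23, -0.21 and -0.09, and did not pass the threshold in limma's test (adjusted p = 0.9999). With the replicate block the adjusted p was 0.32. Myo1e transcripts were thus present in all 3 KO libraries, on average at 0.884 times the WT level, and a whole-gene value does not show whether an edited site or the protein was altered. The 14 tested genes within 2 Mb on either side of Myo1e had a median difference of 0.03, with a range of -0.13 to 0.14.

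Among other class I myosins, Myo1d was at similar levels in both genotypes, 4.97 ± 0.60 in KO and 4.93 ± 0.56 in WT (SD, n = 3). The list of class I myosins had 5 measured genes, of which 0 passed the threshold, and its median difference was 0.03 (camera adjusted p = 0.73), while its mean was -0.01. Among the other myosins, Myo5a, a vesicle transport motor, differed by 0.19 (SE 0.12) and Myo9a by 0.16 (SE 0.14), both higher in 3 of 3 pairs. The list median of the 15 measured genes was 0.07 (camera adjusted p = 0.17), and without WT 1 the list passed at 0.14.

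No single gene passed the threshold for KO against WT among the 11269 genes tested with limma, with 0 higher and 0 lower. At an unadjusted p under 0.05 there were 23 genes, 11 higher and 12 lower, where uniform p-values would give 563. This fit leaves the split by number in the residual spread, so fewer than 563 are expected even without an effect. The largest difference of any gene was 1.39 in size, and the median SE was 0.20. With the replicate block the median SE was 0.07, 1117 genes had an unadjusted p under 0.05 against the same 563, and 1 gene passed the threshold. With the length and GC correction and the block, 878 genes had an unadjusted p under 0.05, where uniform p-values would give 559. Part of the excess thus went with length and GC content. limma voom on the recovered reads called 0 genes without the block, with 24 at an unadjusted p under 0.05, and 1 gene with the block.

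That gene was Txnip, which encodes thioredoxin-interacting protein, a glucose-responsive inhibitor of glucose uptake. It was named after its values were seen. Txnip was at 5.24 ± 1.70 log2 CPM in KO and 6.20 ± 1.69 in WT (SD, n = 3), and the spread came from the libraries numbered 4, where it was 2.88 higher (SE 0.21) than in those numbered 1 and 2. Within pairs it was lower in KO by -0.73, -1.14 and -1.0. The difference was -0.96, with an SE of 1.12 and an adjusted p of 0.9999 without the block, and an SE of 0.08 and an adjusted p of 0.0043 with the replicate block. With a term for the libraries numbered 4 in place of the block the call ended (adjusted p = 0.48), and no gene passed in limma's test, with 898 at an unadjusted p under 0.05. In libraries 1 and 2 only, no gene passed the threshold, with 756 at an unadjusted p under 0.05.

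**Figure D2:**
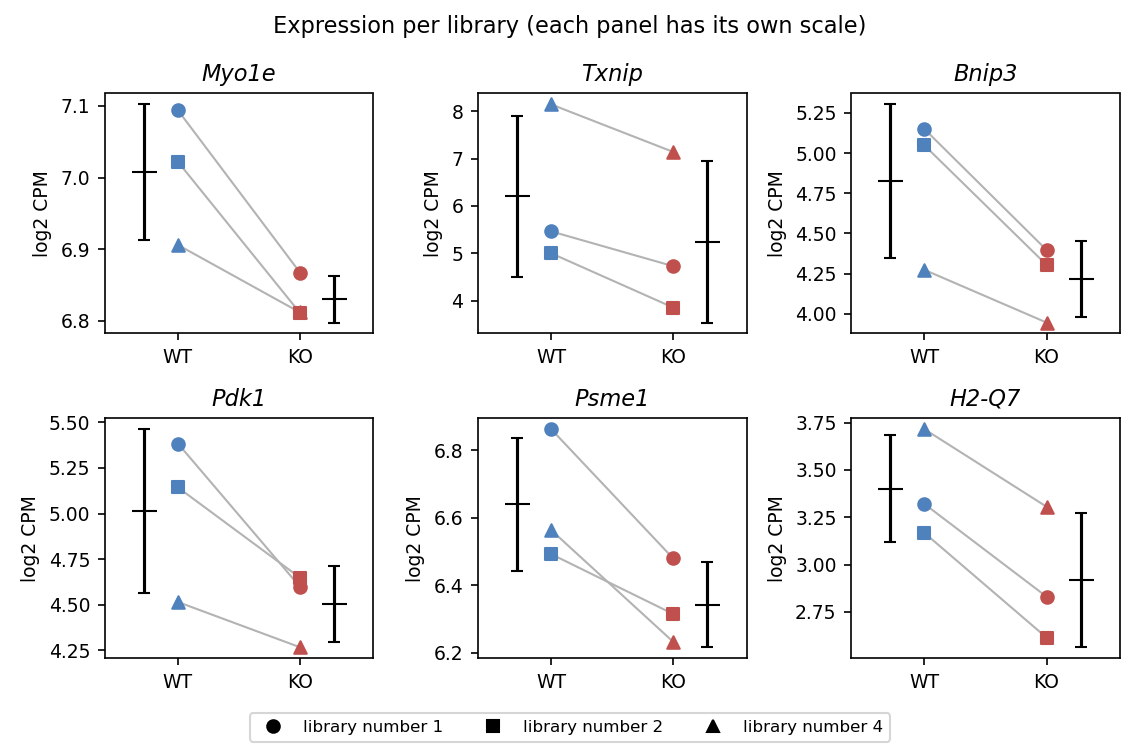
log2 CPM of 6 genes in each library, with WT in blue, KO in red, grey lines joining libraries of the same number, and black bars for the mean ± SD of 3 libraries; each panel has its own scale. All 6 genes are lower in KO in 3 of 3 pairs, by -0.18 on average for Myo1e and by -0.96 for Txnip.

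As groups, 8 of the 37 lists were lower in KO and 2 were higher with camera at its preset correlation. With an estimated correlation 0 lists passed, and fry also called 0. Neither alternative was run in the simulations, so how often they miss a real difference with 6 libraries is not known. Between the libraries numbered 4 and the others, 42 of 42 S phase genes were lower past the threshold. Camera with an estimated correlation still gave that list an adjusted p of 0.67. Failing these tests therefore does not show that a list was unchanged. Within each list, 0 members passed the threshold over all genes, and 0 passed when adjusted over the list alone, without the block. The replicate block gave 9 lists lower and 2 higher.

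Genes of hypoxia and glycolysis were lower in KO, with list medians alike in the 3 pairs. Of 33 measured members 29 were lower, 20 of them in 3 of 3 pairs, and the list median was -0.17 (-11.3%), with pair medians of -0.18, -0.18 and -0.16. Bnip3, a mitophagy receptor induced by hypoxia, was at 4.22 ± 0.24 in KO and 4.82 ± 0.48 in WT (SD, n = 3). Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, was at 4.50 ± 0.21 and 5.01 ± 0.45, and the vasodilator peptide gene Adm at 0.51 ± 0.48 and 1.21 ± 0.27. These 3 genes differed less in the pair numbered 4, by -0.33, -0.25 and -0.40, than in the pairs numbered 1 and 2. The glycolytic enzyme gene Gpi1 was at 8.57 ± 0.11 and 8.73 ± 0.06. The list passed camera's test (adjusted p = 1.3e-06, and adjusted p = 0.69 with an estimated correlation). Without KO 4 the median was -0.05 and the adjusted p 0.051, and without WT 2 or WT 1 the medians were -0.07 and -0.11.

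In this list 15 members were lower with the replicate block when adjusted over the list alone, against 0 over all genes. These 15 were named after their values were seen where the rule does not take them. Besides Bnip3, Pdk1, Adm and Gpi1 they included the carbonic anhydrase gene Car9, with a difference of -0.55, and the glycolytic genes Aldoa (-0.26), Tpi1 (-0.24), Ldha (-0.24), Pgk1 (-0.20) and Pgam1 (-0.17). The glucose transporter gene Slc2a1 differed by -0.14. The list median differed between the libraries numbered 1 and 2 of the same genotype by 0.02 in KO and 0.03 in WT. Between the libraries numbered 4 and those numbered 1 and 2 it differed by -0.32 within KO and -0.34 within WT, a difference that comparison within pairs takes out. The same difference moves the medians given above for single libraries left out.

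Genes of MHC class I antigen presentation were lower in KO, with 24 of 24 measured members below WT on average and 16 below in 3 of 3 pairs. The list median was -0.32 (-19.9%), with pair medians of -0.50, -0.16 and -0.28. H2-Q7, a non-classical class I gene, was at 2.92 ± 0.35 in KO and 3.40 ± 0.28 in WT (SD, n = 3). The immunoproteasome subunit gene Psmb10 was at 5.45 ± 0.15 and 5.78 ± 0.21, and the proteasome activator genes Psme1 and Psme2 differed by -0.30 each, with SEs of 0.14 and 0.18. Camera gave an adjusted p of 3.7e-11, and an adjusted p = 0.69 with an estimated correlation. Leaving out KO 4 or WT 2 moved the median to -0.52 and -0.56, and leaving out WT 4 or KO 2 moved it to -0.11 and -0.18, each still past the threshold.

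Of these members 16 were lower with the replicate block when adjusted over the list alone, against 0 over all genes. Chosen after their values were seen, they included H2-K1 (-0.33) and H2-D1 (-0.32), the classical heavy chains, B2m (-0.27), their light chain, and the peptide transporter genes Tap1 (-0.50) and Tap2 (-0.35). Reads of the H2 genes may be shared between near-identical copies.

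The type I interferon response list was also lower, in 43 of 44 measured members, 20 of them in 3 of 3 pairs. The list median was -0.31 (-19.2%), and the pair medians of -0.66, -0.09 and -0.19 were unequal. Bst2, a membrane tether that holds virus particles, was at 5.03 ± 0.19 in KO and 5.49 ± 0.49 in WT (SD, n = 3), and the antiviral gene Ifitm3 at 6.73 ± 0.09 and 6.97 ± 0.17. Isg20 and Ifi35, 2 further interferon-induced genes, differed by -0.22 (SE 0.11) and -0.29 (SE 0.19). Camera gave an adjusted p of 1.4e-12, and an adjusted p = 0.85 with an estimated correlation. Adjusted over the list alone, 5 members were lower with the replicate block.

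The interferon list also differed between libraries of the same genotype, with a median 0.86 higher in WT 1 than in WT 2 and 0.29 higher in KO 1 than in KO 2. For the MHC class I list the same differences were 0.42 and 0.14. Without WT 4 the interferon median was -0.12 and the call ended (adjusted p = 0.089). Without KO 2 it was -0.14, and without KO 4 or WT 2 it was -0.60 and -0.61, past the threshold each time. In the libraries numbered 4 the interferon and MHC class I medians were higher, by 0.65 and 0.59. The medians with 1 library left out therefore moved in part by construction. Among the chemokines and cytokines, Cxcl10, an interferon-induced chemokine gene, differed by -0.65 (SE 0.43), and that list did not pass (28 measured genes, median -0.08, adjusted p = 0.31), though it did without KO 4 or WT 2, at -0.24 each.

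**Figure D3:**
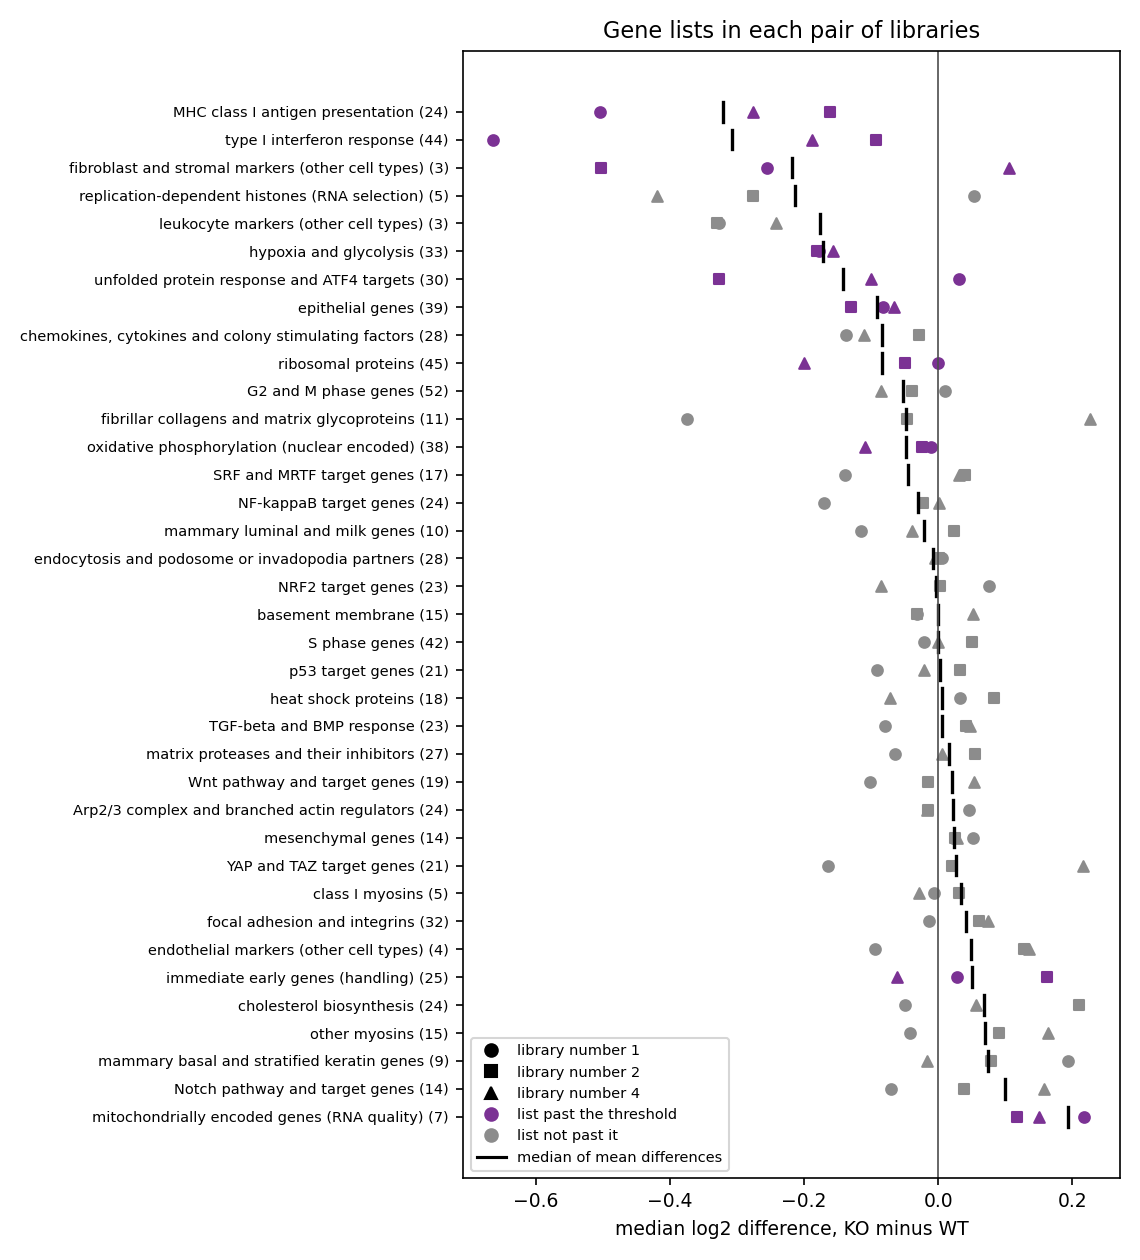
Median log2 difference of each of the 37 gene lists in the pairs of libraries numbered 1, 2 and 4, with the number of measured genes in brackets, a black bar for the median of the mean differences, and purple for lists past the threshold in camera at its preset correlation. The hypoxia and glycolysis list lies between -0.18 and -0.16 in all 3 pairs, and the interferon list between -0.66 and -0.09.

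The list of unfolded protein response genes and ATF4 targets was lower in 30 of 30 measured members on average, with a median of -0.14 and pair medians of 0.03, -0.33 and -0.10. Hspa5, the main chaperone of the endoplasmic reticulum, was at 11.00 ± 0.32 in KO and 11.22 ± 0.48 in WT (SD, n = 3), and Xbp1, a transcription factor of this response, at 6.32 ± 0.21 and 6.57 ± 0.30. Camera gave an adjusted p of 0.019, and an adjusted p = 0.85 with an estimated correlation. The call ended without KO 1 (median -0.01), KO 2 (-0.02) or WT 2 (-0.12), and without WT 4 the median was 0.17. Without KO 4 or WT 1 it was -0.45 and -0.41. In the libraries numbered 4 the list median was 0.88 higher than in those numbered 1 and 2, so these medians moved in part by construction.

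Epithelial genes were lower as a group, with 29 of 39 measured members below WT and a median of -0.09 (camera adjusted p = 0.033, and adjusted p = 0.85 with an estimated correlation). Krt19, a keratin of simple epithelia, was at 6.02 ± 0.22 in KO and 6.28 ± 0.20 in WT (SD, n = 3), and the tight junction gene Marveld2 at 5.08 ± 0.08 and 5.29 ± 0.10. Grhl1, an epithelial transcription factor, was higher in 3 of 3 pairs, at 1.38 ± 0.36 and 0.60 ± 0.27. The call ended without KO 1 (median -0.06), KO 2 (-0.03) or WT 4 (0.0020), and without KO 4 the median was -0.16. After the length and GC correction the epithelial median was -0.051, and the adjusted p was 0.071 without the block and 0.0068 with it. Mesenchymal genes had a median of 0.02 over 14 measured members (adjusted p = 0.68) and a mean of -0.02, and the matrix protein gene Sparc was at 7.08 ± 0.04 in KO and 7.43 ± 0.11 in WT.

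Short transcripts were lower in KO than long ones, and 2 further lists lost their call, blocked or not, after the joint correction for length and GC content. Ribosomal protein genes were lower in 45 of 45 members, with a median of -0.08 (camera adjusted p = 3.2e-07, and adjusted p = 0.85 with an estimated correlation) and pair medians of -0.00062, -0.05 and -0.20. Rplp2 and Rps3, parts of the large and the small subunit, differed by -0.17 (SE 0.12) and -0.16 (SE 0.13). Nuclear genes of oxidative phosphorylation were lower in 35 of 38 members, with a median of -0.05 (adjusted p = 0.019, and adjusted p = 0.85 with an estimated correlation). Ndufb8, a complex I subunit gene, differed by -0.15 (SE 0.12).

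Across 11174 genes with a length, Spearman's rho between transcript length and the KO minus WT difference was 0.187, 0.115 and 0.388 in the pairs numbered 1, 2 and 4, where genes are not independent replicates. For GC content rho was -0.218, 0.031 and -0.019. In libraries 1 and 2 only, the adjusted p was 0.28 for the ribosomal list and 0.54 for oxidative phosphorylation. Without WT 4 the ribosomal median was -0.01 and the call ended, and it was -0.17 without WT 1 and -0.05 without KO 1. For oxidative phosphorylation the call ended without KO 4 (median 0.06), WT 1 (-0.03) or WT 2 (-0.0015). Its median was -0.14, -0.12 and -0.09 without KO 2, WT 4 and KO 1.

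**Figure D4:**
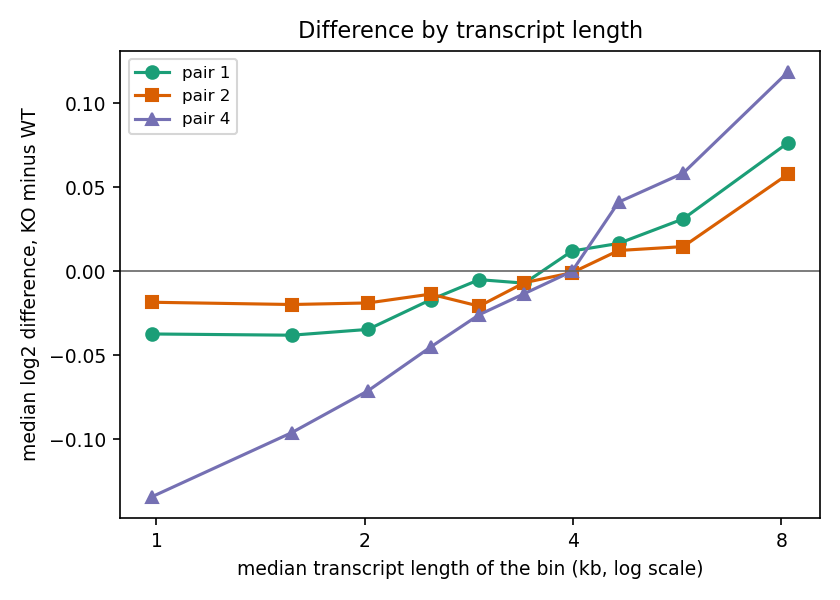
Median log2 difference between KO and WT in bins of genes with equal numbers, ordered by transcript length, with a line for each pair of libraries; the horizontal axis is the median length of a bin in kb on a log scale. In the pair numbered 4 the median goes from -0.13 in the shortest bin (0.986 kb) to 0.12 in the longest (8.18 kb).

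Mitochondrially encoded genes, a sign of RNA quality as well as of mitochondrial content, were higher in KO in 7 of 7 measured members and in 3 of 3 pairs. The list median was 0.19, with pair medians of 0.22, 0.12 and 0.15. mt-Nd5 was at 8.58 ± 0.39 in KO and 8.37 ± 0.43 in WT (SD, n = 3), and mt-Cytb at 9.85 ± 0.27 and 9.69 ± 0.22. Camera gave an adjusted p of 0.028, and an adjusted p = 0.85 with an estimated correlation. Adjusted over the list alone, 5 members were higher with the replicate block. The call ended without KO 1 (median 0.02) or KO 2 (0.13), the median was -0.02 without WT 4, and it was 0.41 and 0.40 without KO 4 and WT 1. In the libraries numbered 4 this list was at -0.65, so these medians moved in part by construction.

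Immediate early genes, which respond to handling, were the other list that was higher in KO, with 18 of 25 measured members and a median of 0.05. Fosl1, a component of the AP-1 transcription factor, was at 7.89 ± 0.19 in KO and 7.69 ± 0.19 in WT (SD, n = 3), and Nr4a2 at 2.36 ± 0.25 and 2.07 ± 0.15. Camera's adjusted p was 0.0498, the adjusted p was 0.85 with an estimated correlation, 0.079 with the replicate block, and 0.011 with the length and GC correction and the block. A minimum of log2 CPM 1, either pseudocount and median centring also ended the call. The call ended without KO 1 (median 0.04), KO 4 (0.02) or WT 2 (-0.09), and the median was 0.16, 0.11 and 0.17 without KO 2, WT 1 and WT 4.

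Markers of other cell types were few in these cultured cells. Of the fibroblast and stromal markers 3 of 18 were measured, Postn, Pdgfra and Gsn, with differences of -0.47, -0.22 and -0.12 and a list median of -0.22 (camera adjusted p = 0.020, and adjusted p = 0.69 with an estimated correlation). The pair medians were -0.26, -0.50 and 0.11, and the call ended when any library but KO 4 was left out, with medians of -0.16, -0.15, -0.23, -0.18 and -0.18 without KO 1, KO 2, WT 1, WT 2 and WT 4. Without KO 4 it was -0.42. The call also ended without genes that another list holds, such as Postn, which is also a mesenchymal gene here. Of the leukocyte markers 3 of 25 were measured, and Cd74, the invariant chain, was at 3.95 ± 1.69 in KO and 4.73 ± 1.35 in WT (list median -0.18, adjusted p = 0.58). The 4 measured endothelial markers had a median of 0.05 (adjusted p = 0.60).

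A further 2 lists were short of the threshold in the main comparison and past it with the replicate block. Genes of cholesterol synthesis had a median of 0.07 over 24 measured genes, with pair medians of -0.05, 0.21 and 0.06. Camera's adjusted p was 0.58 without the block and 0.0017 with it. With an estimated correlation it was 0.92 without the block and 0.83 with it. Lss and Mvd, 2 enzyme genes of that pathway, each differed by 0.18. In libraries 1 and 2 only the adjusted p was 0.013. The list also passed without KO 4, WT 1 or WT 2, with medians of 0.69, 0.47 and 0.32, and without WT 4 as lower in KO, at -0.51. Genes of the G2 and M phases had a median of -0.05 over 52 genes, with a camera adjusted p of 0.24 without the block and 0.014 with it. With an estimated correlation the adjusted p was 0.90 without the block and 0.83 with it. Cdc25c, which activates the mitotic kinase, differed by -0.19 (SE 0.12). The list passed as lower without KO 1, KO 2 or WT 4 (-0.14, -0.12 and -0.19) and as higher without KO 4 (0.15). S phase genes had a median of 0.00036 over 42 genes (adjusted p = 0.88). They passed when any library was left out, at -0.19, -0.24 and -0.44 without KO 1, KO 2 and WT 4, and at 0.42, 0.19 and 0.20 without KO 4, WT 1 and WT 2. In the libraries numbered 4 the cholesterol, G2 and M phase and S phase medians were lower, by -1.72, -0.56 and -1.29. Leaving out 1 library shares these libraries unequally between the genotypes. The calls of both signs thus arose by construction and say little about the genotype.

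The lists nearest to the actin and membrane functions of class I myosins did not pass the threshold with or without the replicate block. The Arp2/3 complex and branched actin regulators had a median of 0.02 over 24 genes (adjusted p = 0.57), with Wipf2 higher by 0.19 (SE 0.10). Endocytosis and podosome partners had a median of -0.0070 over 28 genes (adjusted p = 0.60), and focal adhesion and integrin genes 0.04 over 32 genes (adjusted p = 0.32). Tns4, a focal adhesion adaptor gene, differed by 0.26 (SE 0.16), and the integrin gene Itga1 by -0.44 (SE 0.32). Targets of SRF and MRTF had a median of -0.05 (adjusted p = 0.74), with Tpm2 at -0.66 (SE 0.29), and targets of YAP and TAZ 0.03 (adjusted p = 0.23). Leaving out WT 1 brought focal adhesion genes (0.09) and YAP and TAZ targets (0.12) past the threshold, and leaving out KO 2 the latter (0.08).

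Matrix and signalling lists also stayed short of the threshold without the block. Matrix proteases and their inhibitors had a median of 0.02 over 27 genes (adjusted p = 0.85), where camera's direction was downward. Mmp9, a gelatinase gene, was at 7.38 ± 0.36 in KO and 7.79 ± 0.11 in WT (SD, n = 3). Fibrillar collagens and basement membrane genes had medians of -0.05 and -0.00013 (adjusted p = 0.60 and 0.71). In libraries 1 and 2 only, a comparison chosen after the data were seen, fibrillar collagens (adjusted p = 0.0033) and NF-kappaB targets (adjusted p = 0.030) passed as lower in KO. Over all 6 libraries, camera with an estimated correlation gave each of them an adjusted p of 0.85. The pair medians of the collagens were -0.37, -0.05 and 0.23. Basement membrane genes passed with the length and GC correction and the block (median -0.041, adjusted p = 0.014). Without that correction, camera with the block and an estimated correlation gave them an adjusted p of 0.83. Notch pathway genes had a median of 0.10 (adjusted p = 0.052), Wnt pathway genes 0.02 (0.85) and the TGF-beta and BMP response 0.0056 (0.51). NF-kappaB targets were at -0.03 (0.21), p53 targets at 0.0024 (0.97), NRF2 targets at -0.0035 (0.79) and heat shock proteins at 0.0051 (0.58), each as the list median with camera's adjusted p. Mammary luminal and basal lists had medians of -0.02 and 0.07 (0.79 and 0.58), and the 5 measured replication-dependent histones -0.21 (0.31). NF-kappaB targets passed without KO 4 or WT 2 (-0.27 and -0.18), basal genes without KO 4 or WT 1 (0.66 and 0.51) and heat shock proteins without KO 4 (0.19). In the libraries numbered 4 these lists were at 0.56, -1.51 and -0.58, so their medians moved in part by construction. Without WT 1, Notch genes (0.12) and the histones (-0.52) passed.

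By chromosome, the median differences lay between -0.05 and 0.02. Chromosome 7 had a median of -0.05 over 837 genes, with -0.06, -0.03 and -0.06 in the pairs, and was the only chromosome past the threshold in camera (adjusted p = 0.0035). With the replicate block 6 chromosomes passed, and with the block and an estimated correlation 0 passed, with adjusted p of 0.13 or more. The call on chromosome 7 ended without KO 1, KO 4, WT 2 or WT 4.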

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

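The tests on recovered reads, with a term for the libraries numbered 4, on libraries 1 and 2 only, with the length and GC correction, and with the replicate block joined to another list test were chosen only after the data were seen. All other settings were fixed beforehand. Counts of genes higher in KO, and of genes at least 2-fold higher or lower, were 0 under each setting run. The count of genes lower in KO was 0 in the main comparison and 1 with the replicate block, 1 with voom on reads and the block, and 1 with the length and GC correction and the block, and the gene was Txnip each time. The Myo1e difference kept its sign and stayed short of the threshold throughout, from -0.23 to -0.13 when single libraries were left out. Of the other 144 named genes, 1 passed the threshold under any setting, and 38 turned in sign under at least 1 of 21 settings without passing it there. Median centring and quantile normalization moved the median of all genes by under 0.01 (log2).

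The replicate block also brought the cholesterol synthesis and G2 and M phase lists past the threshold and ended the call on immediate early genes. It changed no other list call. Lists lower in KO numbered 8, 0 with an estimated correlation, 0 with fry, 0 with either of these and the replicate block, and 5 with the length and GC correction. They numbered 7 without genes that another list holds, where the fibroblast and stromal list lost its call. Lists higher in KO numbered 2, and 1 with a minimum of log2 CPM 1, with either pseudocount, with median centring and with voom on reads. They numbered 4 with voom and the block, and 0 with an estimated correlation or fry, blocked or not. An estimated correlation allows for members that vary together, but its power with 6 libraries was not tested. Chromosomes past the threshold numbered 1, and 6 with the replicate block, with a term for the libraries numbered 4, and with the length and GC correction and the block. The cause was not tested. The median of oxidative phosphorylation was 0.0019 after the length and GC correction, with or without the block.

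Leaving out 1 library left the numbers 1, 2 and 4 in unequal shares of the genotypes, so that lists on which the libraries numbered 4 stand apart moved by construction. Lists lower in KO numbered 6 to 8, lists higher 0 to 9 and chromosomes 0 to 1. The lists changed, however: of the 8 lower lists 5 kept their call without KO 1, KO 2 or WT 2, 6 without KO 4 or WT 1, and 3 without WT 4, and 2 to 8 other lists were called. The median ranged from -0.44 to 0.42 for S phase genes, -0.19 to 0.15 for G2 and M phase genes, and -0.51 to 0.69 for cholesterol synthesis. It ranged from -0.45 to 0.17 for the unfolded protein response and ATF4 targets, -0.16 to 0.0020 for epithelial genes, and -0.14 to 0.056 for oxidative phosphorylation. For immediate early genes it ranged from -0.087 to 0.17, and for mitochondrially encoded genes from -0.023 to 0.41. The interferon, MHC class I and hypoxia lists stayed below 0 under each setting run. With single libraries left out, other lists also stayed below 0. These were the ribosomal list (-0.17 to -0.01), the fibroblast and stromal list (-0.425 to -0.15) and the leukocyte list (-0.24 to -0.03). A lasting sign alone therefore does not set a list apart.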

Other observations

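The libraries numbered 4 were singled out because they stood apart, so their differences are given as a description. All the tests in this part, apart from the counts over other splits of the libraries, were chosen only after the values were seen. In the libraries numbered 4, members of the unfolded protein response and ATF4 list moved both ways against those numbered 1 and 2. Of 30 members 19 were higher and 8 lower past the threshold, and the list median was 0.88. The list had an adjusted p of 0.011, and 0.80 with an estimated correlation, under which no list passed here (0.67 or more). Among genes of proteins in the endoplasmic reticulum, Creld2 was at -1.09, Sdf2l1 at -0.96 and Manf at -0.82, whereas Herpud1 was at 1.36, Dnajb9 at 1.08 and Hspa5 at 0.68. Trib3, a target of ATF4, was higher by 4.50 (log2, SE 0.39), by 4.86 in KO and 4.14 in WT. The transcription factor genes Atf3 and Atf5 were higher by 3.35 and 3.31, the growth arrest gene Gadd45a by 3.92, and Nupr1, a stress-induced chromatin protein gene, by 3.54. The type I interferon list had a median of 0.65, with 28 of 44 members higher past the threshold, and the MHC class I list 0.59, with 16 higher and 3 lower.

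Genes of DNA replication and of cholesterol synthesis were lower in the same 2 libraries. S phase genes had a median of -1.29 and were lower past the threshold in 42 of 42 members, with Cdc6, which loads the replicative helicase, at -2.71 and Rrm2, a ribonucleotide reductase subunit gene, at -2.42. Cholesterol genes had a median of -1.72 and were lower past the threshold in 24 of 24 members, among them Cyp51 at -2.48. G2 and M phase genes were at -0.56, basal and stratified keratin genes at -1.51 and heat shock proteins at -0.58. Tfrc, the transferrin receptor gene, was at -2.42, and the hyaluronan synthase gene Has2 at -2.98.

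A technical explanation for the separate position of these 2 libraries is depth, but 0 of the 2 had a read total outside the range of the other 4, which argues against it. Transcript length and GC content were not the whole cause either, since 93.7% of 1276 genes at least 2-fold apart stayed so after the correction. A different state of the cultures, with fewer cycling cells, is a candidate explanation, with the S phase median of -1.29 as the value it rests on. It cannot be told apart from any other cause tied to the number 4, because no label says what the number marks. No biological explanation from the design was tested, since both genotypes share the pattern.

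The lower interferon and MHC class I lists in KO were set against differences between libraries that vary from pair to pair. Differences within a genotype hold the effect of the number, which comparison within pairs takes out. Both lists were lower in 3 of 3 pairs, but the pair medians spanned 0.57 for interferon and 0.34 for MHC class I, as much as the medians themselves (-0.31 and -0.32). With 3 pairs, such differences cannot be told apart from a shared one for these 2 lists. For hypoxia and glycolysis the pair medians spanned 0.024, below the smallest of them in size (0.16). That criterion was set after the like medians were seen, and with 3 pairs it cannot exclude such differences. With the replicate block, this list had an adjusted p of 0.51 in camera with an estimated correlation and 0.16 in fry. Length and GC content did not account for the 3 lists, whose medians were -0.30, -0.27 and -0.14 after the correction. RNA quality and reads from cells of another type stay open for the 3 lists. Mitochondrially encoded genes were higher in KO in 7 of 7 members. Only 3 of 25 leukocyte markers and 3 of 18 fibroblast and stromal markers were measured, so the case for reads from other cells rests on few genes. The 3 measured leukocyte markers had pair medians of -0.33, -0.33 and -0.24, with 2 lower and 1 higher on average. An effect of the Myo1e genotype also stays open for each list as a hypothesis. It cannot be told apart from any other lasting difference between the KO and WT pools, whose derivation is not given.

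The lower ribosomal protein and oxidative phosphorylation lists may come from a bias by transcript length and GC content. After the correction the medians were -0.018 and 0.0019, from -0.08 and -0.05, and with the replicate block the adjusted p rose to 0.10 and 0.96 because the medians shrank. The trend on length was steepest in the pair numbered 4 (rho 0.388) and that on GC content in the pair numbered 1 (rho -0.218). The correction took out both together, so their shares were not separated. Whether the bias arose in library preparation or in the cells was not tested.

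Other splits of the libraries bear on how far chance can be excluded. The 10 splits into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes and the highest other 0. All 10 splits reach a real value of 0 whatever the data, so this count bears nothing on chance. For lists the real value was 10 and the highest other 17, with 6 of the 10 splits at the real value or above. Among the 4 splits that part all 3 pairs, fitted with the replicate block and likewise too few, the real value was 1 gene and the highest other 1, with 2 splits at that value. The others differ from the real split by exchanging KO and WT within 1 pair. For lists the real value was 11, the highest other 17, and 3 splits reached the real value. At an unadjusted p under 0.05 the real blocked split had 1117 genes and the highest other 562. The real blocked split had 878 after the length and GC correction, with which the other splits were not run. Splits that put both libraries numbered 4 on the same side had up to 2660 genes at an unadjusted p under 0.05, against 23 in the real unblocked split, which points to the structure by number described above.

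Between pairs the single-gene differences shared little. Across 9192 genes with a mean log2 CPM above 3, the KO minus WT differences of the pairs numbered 1 and 2 correlated at r = 0.243, those of 1 and 4 at 0.063 and those of 2 and 4 at 0.108, where genes are not independent replicates. The sign was the same in all 3 pairs for 33.8% of genes, against 25% by chance. The 25% allows for no trend shared by the pairs. The trend on transcript length was upward in each pair (rho 0.187, 0.115 and 0.388), and the agreement was not computed after the length and GC correction. How much of it reflects the genotype is therefore not known.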
